A study of Mus musculus with 72 samples.

How the data were processed

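RNA was sequenced from mouse liver and quadriceps muscle in 72 samples, which the labels place in 12 groups of 6. The deposited table holds whole-number counts per Ensembl gene, and the submitters' processing notes name STAR and featureCounts without versions. Apart from a check that the values are whole numbers, only the column names and the gene identifiers of this table were read here. The names of 72 of its 72 value columns matched no sample or group in the labels, so none of these columns was used in any other step. No filter, normalisation or test was applied.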

Results

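No expression value is reported for this series, because the columns of its count table were not matched to the samples. According to the labels, RNA was sequenced from the liver and the quadriceps muscle of male mice during an insulin clamp, a procedure in which insulin is infused into a vein while glucose is given to hold blood glucose steady. Mice received saline, 4 or 12 mU/kg/min insulin, and tissue was taken at 20 min or 3 h. The 72 samples form 12 groups of 6, one for each tissue, infusion and time. The labels do not tie liver and muscle samples of the same mouse to each other.

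The design implies comparisons of each insulin infusion with saline within a tissue and time, of the higher with the lower infusion, of the later with the earlier time, and of liver with muscle. None of these comparisons was made. The count table listed 46071 mouse Ensembl gene identifiers, of which 45143 had a name in the GENCODE reference table used here. Its 72 value columns carried codes in place of sample titles, and 0 of these codes occurred in any label. Column order and gene values were not used to assign columns to tissues, infusions or times. Depth per sample, replicate spread and the response of individual genes to insulin are therefore not analysed here.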

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

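The number of columns matched to a sample by name was 0 with exact names. It was also 0 when letters and digits alone were compared and 0 when the digits of each code were sought in the labels. These other ways of comparing names were chosen after the table was seen. The fits and alternatives fixed before the data were examined were not run, since each needs the group of every column. No analysis by group was made, because no column was matched by name to a group in the labels used here. A paired analysis of liver with muscle would also need the mouse of each sample, which the labels do not give.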
